A study of Mus musculus with 4 samples.

How the data were processed

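Bone marrow-derived dendritic cells of WT and GOLPH2 KO mice (C57BL/6, 8 weeks old) gave 4 libraries, 1 for each genotype without stimulation and 1 for each genotype after IFN-gamma for 16 h and LPS for 4 h. Per the labels' protocols, total RNA was isolated with a column kit (RNeasy) and libraries were made with a strand-specific Illumina TruSeq mRNA preparation. Per the submitters' processing notes, FastQC 0.10.1, HTSeq 0.6.0 and the genome build mm10 were used; the aligner, the gene annotation, the strand setting of the counting, the scaling between libraries and the test are not given in the sources used here. Groups were taken from the sample titles.

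The authors deposited 2 tables of comparisons, KO over WT in unstimulated and in stimulated cells. Per the file headers, the first measure is a log2 fold change per gene. The second measure is named as a log10 p-value per the file headers and holds, from its values, −log10 p as deposited by the authors, with no value above 100 in the unstimulated and 150 in the stimulated table. Further columns repeat both measures for genes the authors marked as differentially expressed and as key genes. The marked genes were recovered exactly (161 of 161 and 159 of 159) by a deposited fold change above 1.5 in either direction and a Benjamini-Hochberg adjusted p under 0.001, computed from the deposited p-values; this reading comes from the values. Per-library values were not analysed here, so depth per library is unknown and no stimulation response was computed.

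The deposited fold changes are not centred where the p-values are. The deposited p is closest to 1 at a log2 ratio of 0.191 in unstimulated and −0.036 in stimulated cells, and the median gene lies at 0.193 and −0.031. Each deposited log2 ratio was therefore reduced by this zero point of the authors' test, which is an own derivation and the main scale of the text. The ratios as deposited and the ratios centred on the median gene were used as alternatives. The counting SE of a gene was derived as its centred log2 ratio divided by the normal deviate of its two-sided deposited p. Its highest values, 2.038 and 2.039, lie at that of 1 read against 1 read (2.040), so the deposited p-values hold counting error only and no spread between cultures. For the 51 and 50 genes at the highest deposited −log10 p, this SE is an upper limit. The 10th and 90th percentiles of the SE were 0.030 and 0.964 in unstimulated and 0.031 and 0.991 in stimulated cells.

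A gene was called where the Benjamini-Hochberg adjusted p over the genes of its table was under 0.001, with its direction taken from the centred ratio. The design fixed before the data were examined assumed values per library. It classed genes by a size rule of 2-fold with an expression floor; without expression values, the floor was replaced by this threshold, which is the authors' own. The genes named were fixed by rule: Golm1, all members of the IL-12 list, 2 to 4 members of each other list with the largest ratios, and the 10 highest and 10 lowest genes that pass the size rule, leaving out unnamed gene models, pseudogenes and microRNA and small nucleolar RNA genes. List members under 2-fold are given as values. A few genes that the rule names are not reported here. The same rule was used for the agreement and the difference between states. Of the 27 gene lists fixed before the data were examined, the Golm1 list and the sex-linked list (Xist alone was listed) had fewer than 3 listed members and got no median. Lists of fibroblast and of endothelial markers (2 lists) were added after seeing the data.

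For each list, the median ratio was placed among the medians of 10000 random lists of the same size, matched on counting SE in 20 bins, with the list's own members left out. Mean expression, the matching planned, was not used since it was not in the tables. The percentile describes these libraries and is no test of the conditions. Gene positions came from the RefSeq annotation of GRCm38.p6, the build named mm10 in the notes, by symbol or synonym; 15785 of 15881 genes (99.4%) matched to 1 position.

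The procedure was tested on simulated data with 200 genes changed by known folds in each table. The changed genes were drawn only from genes with a counting SE no larger than that of 50 reads per library. Genes with a larger SE were not simulated as changed, so the shares called do not cover them. At 1.5-fold the procedure called 80% of the changed genes in the unstimulated table (15394 genes) and 86% in the stimulated table (15310 genes). At 2-fold the shares were 88% and 96%, and at 4-fold 100% in both tables, with 0 false calls. The simulated noise was counting error alone. These shares and the 0 false calls therefore leave out the spread between cultures, which the data hold. Of 40 unchanged lists, 35 and 37 fell in the central 95% of random lists, and 40 of 40 shifted lists were found in each table. The shift was larger than most list medians given below, so the finding of smaller shifts was not tested. These lists held genes drawn at random, with independent noise.

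The genotype term of the additive model (state and genotype) is the mean of the KO over WT ratios of both states, with state as a block and 1 residual degree of freedom. It was fitted with limma to the centred ratios, with empirical Bayes variances following the counting SE, for the 10986 genes with an SE no larger than that of 50 reads in both states, and called at a Benjamini-Hochberg adjusted p under 0.05. The design had asked for values per library on 1 scale, and this fit on ratios was chosen after seeing the data. With 1 residual degree of freedom the prior degrees of freedom are weakly fixed. They were 12.2, 6.05 with centring on the median gene, 16.1 without a filter, and infinite with the ratios as deposited. A cause that differs between the cultures of the genotypes in both states enters this term. In 10986 simulated genes, 200 of them changed, the fit called 92% at 1.5-fold and 100% at 2-fold or more, with 14 false calls. The simulated noise was independent between the states. The 14 false calls therefore leave out any difference that the cultures of a genotype share in both states.

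Not run, since the tables hold no value per library, were the planned stimulation responses of both genotypes, the stimulation term of the additive model, the alternatives of the genotype term with DESeq2, the exact interval of count ratios, the alternatives of the prior count, and the floors of 10 and 200 reads. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.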

Results

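Dendritic cells grown from the bone marrow of 8-week-old C57BL/6 mice, either wild type (WT) or lacking GOLPH2 (KO), were profiled by strand-specific mRNA sequencing. GOLPH2 is a membrane protein of the Golgi apparatus encoded by Golm1. Cells of each genotype were left unstimulated, or were primed with IFN-gamma for 16 h and then given the bacterial cell wall component LPS for 4 h. This gave 4 libraries in 4 groups, 1 library per group, so no difference within a state has a replicate check. The authors' deposited tables compared KO with WT in each state and listed 15394 genes for unstimulated and 15310 genes for stimulated cells. Read totals per library were not analysed here. The precision of each ratio was therefore taken from the authors' p-values as a counting error, with a median of 0.088 in unstimulated and 0.092 in stimulated cells on the log2 scale. Errors given below as ± are this counting standard error (SE); it covers the sampling of reads only and not the difference between cultures. Ratios are log2 of KO over WT, centred as described under processing, and a gene is said to be called where the Benjamini-Hochberg adjusted p of the authors' deposited p-values was under 0.001. Such a call compares 2 libraries, not 2 conditions.

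The targeted gene was examined first. Golm1 (chromosome 13, 59634996 to 59675784, GRCm38, protein-coding) was lower in the KO library in both states, at −2.09 ± 0.098 in unstimulated and −2.00 ± 0.10 in stimulated cells. These ratios correspond to 23.5% and 25.0% of the WT level. The tables give 1 value for the whole gene, and the part of Golm1 removed in the knockout is not given in the sources used here.

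The comparison of unstimulated cells asks how loss of GOLPH2 alters the transcripts of resting dendritic cells. Collagen and other matrix genes were among those with the highest ratios in the KO library, and Il12b, Tlr2, Il6 and Cxcl1 were among the genes called lower. Among the genes called at 2-fold or more, the 10 with the highest ratios were Col8a1 (4.20 ± 0.95), Col3a1 (3.06 ± 0.58), Mid1 (3.04 ± 0.14), Cyr61 (2.84 ± 0.54), Fbln2 (2.01 ± 0.26), Lamb1 (1.67 ± 0.34), Col1a2 (1.36 ± 0.29), Ctgf (1.30 ± 0.25), Col5a2 (1.23 ± 0.22) and Fn1 (1.07 ± 0.09). Of these, Col8a1, Col3a1, Col1a2 and Col5a2 encode collagen chains, Fn1 fibronectin, Fbln2 fibulin and Lamb1 a laminin chain. The 10 lowest were Capn11 (−5.51 ± 0.81), Nxpe4 (−4.10 ± 1.04), Golm1, Spic (−1.75 ± 0.37), Bmp2 (−1.64 ± 0.37), Cryab (−1.46 ± 0.30), Rnf125 (−1.44 ± 0.27), Slc40a1 (−1.35 ± 0.13), Lars2 (−1.30 ± 0.06) and Itih1 (−1.26 ± 0.30). Slc40a1 encodes the iron exporter ferroportin, and Spic a transcription factor of iron-handling macrophages. The ratios of Col8a1, Nxpe4 and Capn11 carried counting errors of 0.81 or more, and their size is poorly fixed.

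In unstimulated cells the stromal and endothelial marker list had 13 members. Of these, 4 were called higher (Col3a1, Col1a2, Fn1 and Thy1, the last at 0.40 ± 0.04) and 0 lower, with a list median of 0.62. That median lay above the central 95% of medians of random lists matched on counting error, which reached from −0.13 to 0.20. In the IL-12 family, whose product IL-12 drives type 1 helper T cell responses, Il12b (−0.68 ± 0.04) and Il12a (−0.61 ± 0.09) were called lower, and Ebi3 (0.05 ± 0.04), Il23a (−0.01 ± 0.25) and Il27 (−0.06 ± 0.22) were not called. Inflammatory cytokines had 5 of 15 listed members called lower, among them Il6 (−0.56 ± 0.03), Csf1 (−0.55 ± 0.03) and Ptgs2 (−0.52 ± 0.02). The lymphotoxin gene Lta (0.72 ± 0.11) was the single member called higher, and the list median of −0.14 lay at percentile 0.16 of the random lists; it was −0.23 over the members with a counting error no larger than that of 50 reads per library. The Toll-like receptor and NF-kB list had 8 of 29 members called lower and 3 higher, with a median of −0.06 at percentile 1.02. Tlr2, a receptor for bacterial lipoproteins, was at −0.99 ± 0.05, and Cd14, the co-receptor for LPS, at −0.51 ± 0.02. With the ratios as deposited rather than centred, the medians of both lists were above 0, at 0.047 for inflammatory cytokines and 0.13 for the Toll-like receptor list. Chemokines went both ways, with 8 of 21 called higher, such as Ccl4 (0.58 ± 0.04), and 6 lower, such as Cxcl1 (−0.67 ± 0.03) and Ccrl2 (−0.67 ± 0.03). The type I interferon list had 7 of 32 members called higher and 2 lower (median 0.05), and the interferon-gamma list 4 of 28 higher and 3 lower (median 0.06). As deposited, these medians were 0.24 and 0.25.

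Markers of cell identity also differed between the unstimulated libraries. Of 21 listed macrophage and monocyte markers, 10 were called higher and 5 lower, with the complement genes C1qb (2-fold, with a counting error of 0.15 on the log2 scale) and C1qc (0.74 ± 0.14) and the Fc receptor gene Fcgr1 (0.66 ± 0.05) at the upper end. Dendritic cell markers had 6 of 16 called higher and 1 lower, led by Clec10a (0.84 ± 0.11) and Batf3 (0.51 ± 0.04). Costimulation and maturation genes had 10 of 22 called higher and 3 lower, all within 1.5-fold. Of 11 class II antigen presentation genes, 2 were called higher and 0 lower, and H2-Ab1 was at 0.09 ± 0.01. The median matched random list had 1 call in each direction. Of 16 listed class I antigen presentation genes, 6 were called higher and 0 lower. The regulatory and feedback list had 5 of 18 called higher and 5 lower, including Arg1 (0.56 ± 0.03) and the inhibitor of Toll-like receptor signalling Irak3 (−0.52 ± 0.05). Its counts were at percentiles 75.4 and 92.0 of matched random lists, whose medians were 4 higher and 3 lower. Lymphocyte markers were mostly at low precision, with 1 of 15 called higher, Gzma (0.86 ± 0.16), and a median of 0.39, above the central 95% of random lists (−0.21 to 0.33). Neutrophil markers had 2 of 15 called lower (Lcn2 and Mmp8), mast cell, basophil and eosinophil markers 1 of 9 (Hdc), and plasmacytoid (8 listed) and erythroid markers (3 listed) had 0 called in either direction.

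In total 1380 genes were called in unstimulated cells, 723 higher and 657 lower after centring against 1010 higher and 369 lower as deposited. At 1.5-fold or more, 63 were higher and 46 lower, so that 57.8% were higher; in the authors' deposited table, whose marked genes follow the same thresholds without centring, 139 of 161 (86.3%) were higher. At 2-fold or more, 14 were higher and 13 lower. The authors' zero point lay at a deposited log2 ratio of 0.19, and 74.0% of the genes were within 1.2-fold of it.

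**Figure D1:**
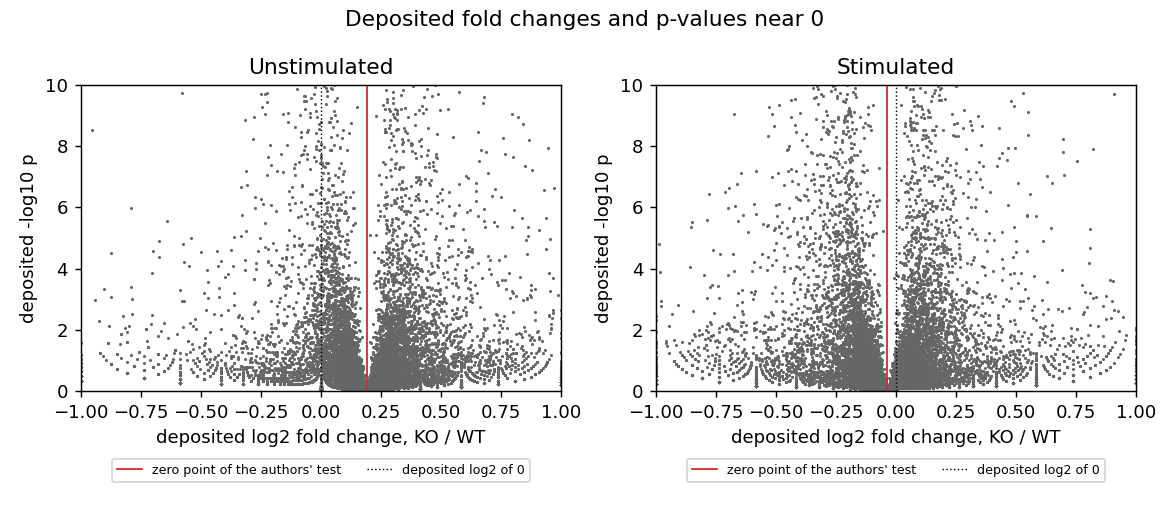
Deposited log2 fold change of KO over WT (x axis) against the deposited −log10 p (y axis) for each gene near 0, in unstimulated (left) and stimulated cells (right); the red line marks the ratio at which the authors' test gives a p of about 1, and the dotted line a deposited log2 of 0. The red line lies at 0.19 in unstimulated and at −0.04 in stimulated cells.

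The comparison of stimulated cells asks the same question after IFN-gamma and LPS. Interferon-induced genes were lower in the KO library as a group, and collagen genes were again among those with the highest ratios. Of 33 listed members of the type I interferon response, 30 were called lower and 0 higher, 13 of them by 1.5-fold or more. Examples were the antiviral effectors Ifit2 (−1.17 ± 0.04) and Ifit3 (−1.14 ± 0.04), Cmpk2 (−1.07 ± 0.04) and Mx2 (−0.97 ± 0.04). The members not called were Ifnb1, which encodes interferon-beta (0.28 ± 0.34), Bst2 (−0.01 ± 0.02) and Ifi205 (0.05 ± 0.02). The list median was −0.48, and the central 95% of the medians of matched random lists reached from −0.05 to 0.05; the highest number of lower calls in any of the 10000 random lists was 16. The interferon-gamma list had 22 of 28 members called lower and 2 higher, with a median of −0.35, led by Ido1 (−0.99 ± 0.15), Irgm2 (−0.75 ± 0.03) and Gbp9 (−0.73 ± 0.03). Its members called higher were Serpina3g (0.33 ± 0.04) and Socs1 (0.11 ± 0.02). Ifit3, the Gbp, Oas and Irgm families and Tgtp1 have close paralogs whose reads the authors' counting could have split, so single values in these families are less certain than the list.

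Among genes called at 2-fold or more in stimulated cells, 8 of the 10 highest were Col3a1 (6.27 ± 0.40), Pcsk5 (5.56 ± 1.11), Col1a1 (3.51 ± 0.19), Igfbp3 (3.39 ± 0.57), Ngfr (3.04 ± 0.70), Fgf7 (2.91 ± 0.72), Col5a2 (2.86 ± 0.18) and Igfbp5 (2.81 ± 0.35). The 10 lowest were Capn11 (−5.61 ± 1.09), the imprinted non-coding RNA H19 (−5.13 ± 1.18), Cited1 (−2.55 ± 0.65), Golm1, Sprr2e (−1.96 ± 0.51), Adam12 (−1.70 ± 0.44), Hamp2 (−1.70 ± 0.06), Myo18b (−1.62 ± 0.33), Itih1 (−1.59 ± 0.32) and Ackr3 (−1.49 ± 0.38). The stromal and endothelial list had 6 of 13 members called higher, with Sparc (1.99 ± 0.20) and Fn1 (1.43 ± 0.07) beside the collagens, and 1 lower, the endothelial receptor gene Kdr (−0.41 ± 0.08); its median was 0.82.

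Among cytokine and receptor genes of stimulated cells, Il12b (−0.83 ± 0.03) was called lower, and Il12a (−0.18 ± 0.05), Il27 (−0.25 ± 0.07), Il23a (0.10 ± 0.10) and Ebi3 (−0.01 ± 0.03) were not called. Inflammatory cytokines had 6 of 15 called lower, led by Il15 (−0.48 ± 0.04) and Csf1 (−0.37 ± 0.03), and 2 higher, led by Lta (0.61 ± 0.08). The median of this list was −0.16. Chemokines had 12 of 21 called higher, among them Ccl17 (0.60 ± 0.02) and Ccl8 (0.53 ± 0.13), and 5 lower, of which the interferon-induced Cxcl11 (−0.82 ± 0.17) and Cxcl10 (−0.63 ± 0.03) were lowest. The Toll-like receptor and NF-kB list had 11 of 29 called lower, led by Tlr3 (−0.98 ± 0.11) and Tlr2 (−0.65 ± 0.03), and 2 higher. Regulatory and feedback genes were 6 higher and 6 lower of 18, with Ido1 lowest and Arg1 (0.61 ± 0.02) highest. For this list, matched random lists had medians of 5 higher and 4 lower calls.

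In the same stimulated cells, class I antigen presentation genes had 7 of 16 called lower and 3 higher. Their median was −0.09, and −0.04 over the members with a counting error no larger than that of 50 reads per library. Class II genes had 1 of 11 called lower and 2 higher, the same as the medians of matched random lists (1 lower and 2 higher). Costimulation and maturation genes had 11 of 22 called higher, led by Pdcd1lg2 (0.41 ± 0.02), and 5 lower, led by Tnfsf4 (−0.50 ± 0.06). Macrophage and monocyte markers had 9 of 21 called higher and 4 lower, again with C1qb (0.94 ± 0.15) and C1qc (0.65 ± 0.15) among the highest. Dendritic cell markers had 7 of 16 called higher and 1 lower, with Clec10a at 0.86 ± 0.15 and Batf3 at 0.57 ± 0.04. Of 15 lymphocyte markers, Gzmb (0.68 ± 0.15) alone was called, and the list median was 0.52. Neutrophil markers (11 listed) had 1 member called lower, Lcn2, and mast cell, basophil and eosinophil markers (6 listed) also 1, Hdc. Plasmacytoid (8 listed) and erythroid markers (3 listed) had 0 called.

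In stimulated cells 1822 genes were called, 821 higher and 1001 lower. At 1.5-fold or more, 65 were higher and 91 lower, against 57 and 102 marked in the authors' deposited table. At 2-fold or more, 35 were higher and 23 lower. With no replicate, a difference between the 2 cultures in the strength of stimulation or in their cell content is part of each of these ratios.

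**Figure D2:**
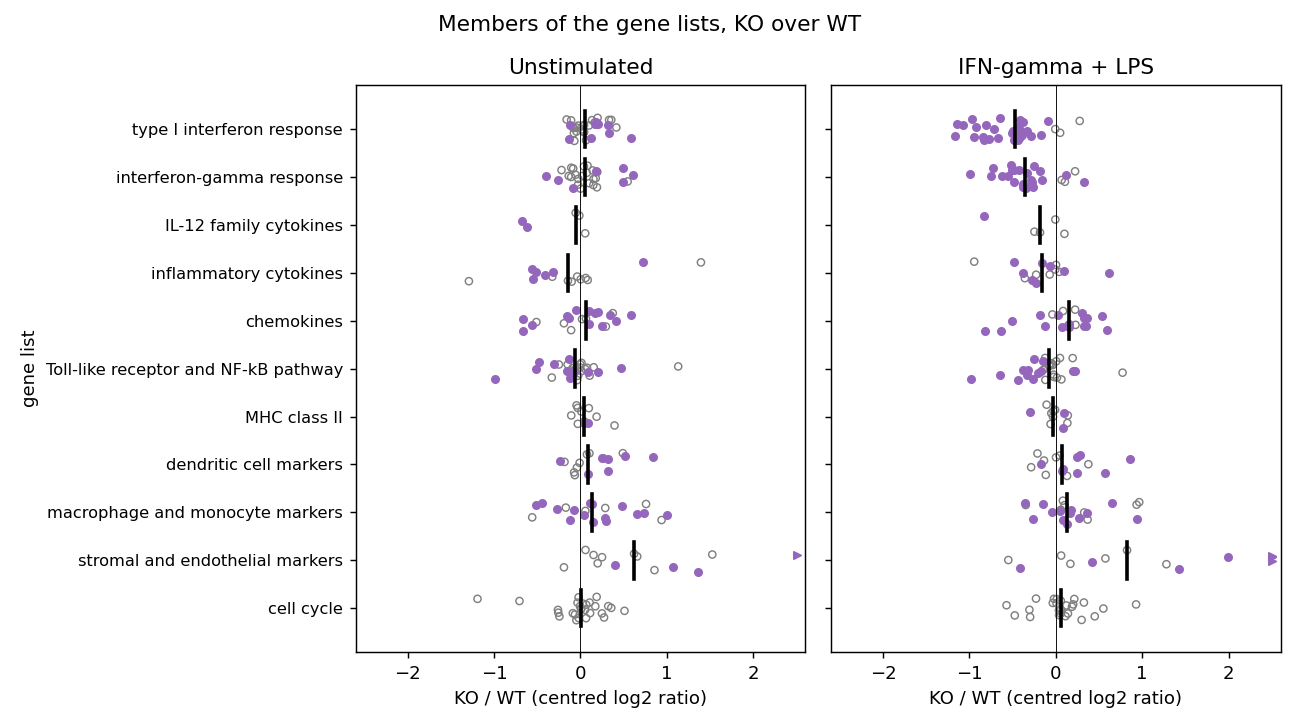
Centred log2 ratios of KO over WT (x axis) for the members of 11 gene lists (y axis) in unstimulated (left) and stimulated cells (right); filled points were called at an adjusted p under 0.001, open points were not, arrowheads lie beyond the axis, and black bars are list medians. The type I interferon list has its median at 0.05 in unstimulated and at −0.48 in stimulated cells.

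The comparison of both states asks which genotype differences recur, since the ratios of each state come from separate libraries. Of the 14823 genes in both tables, 9 were called 2-fold higher in both states and 4 lower in both. Independent lists would share 0.033 and 0.018 genes. The 9 higher genes were Col3a1, Mid1, Fbln2, Lamb1, Col1a2, Col5a2, Fn1, Erdr1 and Cald1, and the 4 lower genes were Golm1, Capn11, Itih1 and Rnf125. At 1.5-fold, 26 were higher and 14 lower in both, including Il12b and Tlr2 on the lower side and C1qb, C1qc, Clec10a and Lta on the higher side. At any size, 439 were called higher in both and 331 lower in both, where independent lists would share 40.04 and 44.3. In opposite directions 41 were called, where independent lists would share 85.1. These expected numbers take every gene as equally likely to be called. Genes of low counting error are called more readily in both states, so the numbers expected at any size are too low. Across genes, which are not independent replicates, Pearson's r was 0.16 and Spearman's rho 0.29; over the 10986 genes with a counting error no larger than that of 50 reads in each library, r was 0.50 and rho 0.45. The genotype term of an additive model (state and genotype, limma), which takes the 2 states as repeats and the difference between them as error, was fitted to these 10986 genes. At an adjusted p under 0.05, 503 were higher and 469 lower, among them Golm1 (mean −2.04), Tlr2 (−0.82) and Il12b (−0.76) on the lower side and Mid1 (2.67), Col5a2 (2.05) and Fn1 (1.25) on the higher side. These counts were 254 and 220 with centring on the median gene, so the number of such genes is poorly fixed. With the ratios as deposited they were 45 and 12. There the unlike zero points of the 2 states (0.191 and −0.036) enter the error of every gene, so this drop does not measure how firm the counts are. Whether the cultures of a genotype in both states came from the same mice is not given in the labels.

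**Figure D3:**
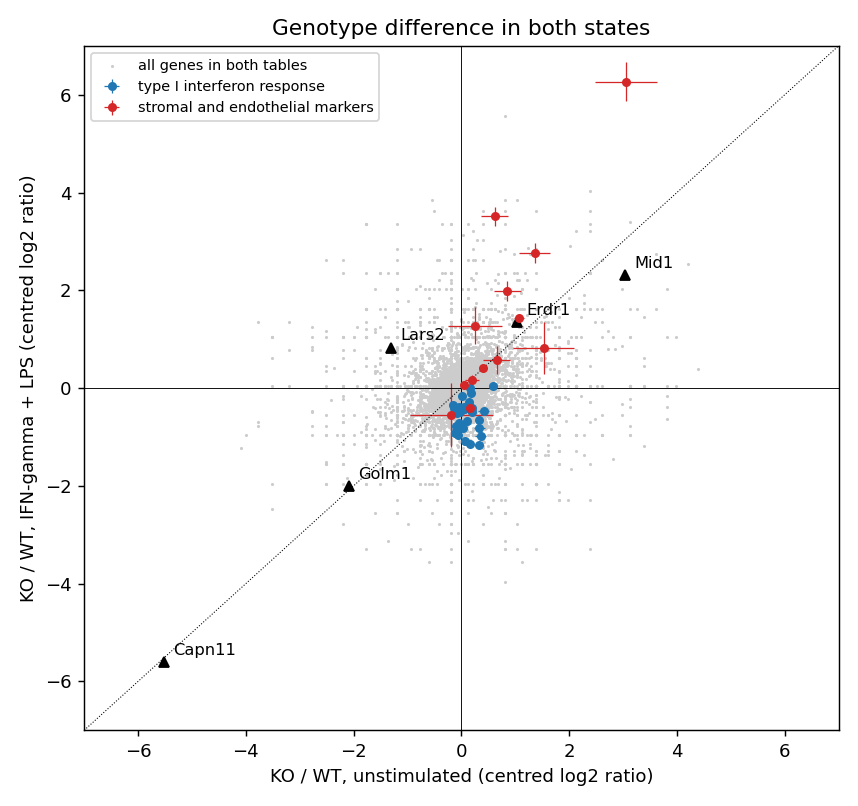
Centred log2 ratio of KO over WT in unstimulated (x axis) and stimulated cells (y axis), with 1 grey point per gene in both tables; blue points are type I interferon response genes, red points stromal and endothelial markers, bars counting SE, triangles named single genes, and the dotted line equal ratios. Golm1 lies near that line at −2.09 and −2.00, and the blue points lie below it, apart from a few near the line.

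The difference between the states, the interaction implied by the design, has no residual degrees of freedom and is given as values. Of the genes called in at least 1 state, 22 had a ratio that was higher by 2-fold or more in stimulated cells and 19 one that was lower. On the higher side were Pcsk5 (4.75 ± 2.04), Col3a1 (3.21 ± 0.70), Col1a1 (2.89 ± 0.32), Nxpe4 (2.87 ± 1.27), Ngfr (2.74 ± 1.09), Lars2 (2.13 ± 0.07), Igfbp5 (2.09 ± 0.49), Il13ra2 (1.79 ± 0.63) and Tnc (1.66 ± 0.27). The lower side was led by Cyr61 (−2.05 ± 0.66), Cited1 (−2.00 ± 0.97), the death ligand gene Tnfsf10 (−1.87 ± 0.34), Col8a1 (−1.66 ± 1.22), Ifit2 (−1.50 ± 0.08), Hamp2 (−1.44 ± 0.08), Mx2 (−1.33 ± 0.11), Ifit3 (−1.30 ± 0.09), Adam12 (−1.25 ± 0.75) and Ifi44 (−1.16 ± 0.11). Of the differences named, those of Col8a1 and Adam12 were within 2 counting errors. With the ratios as deposited, 16 genes were on the higher and 38 on the lower side.

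The authors' deposited tables also mark a short list of key genes, 13 in unstimulated and 12 in stimulated cells. In the authors' deposited table of unstimulated cells these ranged from Golm1 at −1.90 to Col3a1 at 3.25 as deposited, and included Bmp2, Rnf125, Myc, Gzma, Il31ra and Fn1. For stimulated cells the authors' deposited table marked Cited1 at −2.58 as the lowest and Fgf7 at 2.87 as the highest, together with Tnfsf10, Ifit2, Ifit3, Ido1, Ifng, Il13ra2 and Tnc. Ifng, which encodes IFN-gamma, was at 1.17 ± 0.28 after centring. Since the study chose these genes on the same libraries, their directions are not independent evidence.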

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

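The tests in this part were chosen after the results were seen. Of the 41 genes called in opposite directions in the 2 states, the 1 that was at 1.5-fold or more in both is singled out here, with the lists whose medians lay outside the central 95% of matched random lists on opposite sides in the 2 states. None of these differences was tested, since each state has 1 library per genotype. Lars2, the gene of a mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462675, GRCm38), was called lower in unstimulated cells (−1.30) and higher in stimulated cells (0.83), a difference of 2.13 with a counting error of 0.07.

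The medians of the interferon lists also went opposite ways. For the type I interferon list the median was 0.05 in unstimulated and −0.48 in stimulated cells, a difference of −0.53, and for the interferon-gamma list 0.06 and −0.35, a difference of −0.41. The lists overlap in function, and they are not independent of each other.

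For the lower type I interferon list in stimulated KO cells, the values argue against library scaling as the whole cause. One factor moves all genes alike, while the list lay 0.47 below matched random lists (a difference of −0.474), against 0.053 for 2 SD of their medians. The list was flagged by this same comparison, so it is no separate test. Dilution by stromal cells would lower dendritic cell markers alike, and their median was 0.55 above that of the interferon list, against 0.10 for 2 SD of random medians. A uniformly weaker LPS response cannot be told apart. The median of the inflammatory cytokine list was 0.31 above that of the interferon list, against 0.11 for 2 SD. The inflammatory cytokine list was itself low (median −0.16 at percentile 0.14, with 6 members called lower and 2 higher). Other lists went the other way. Chemokines had a median of 0.15 at percentile 100 (12 called higher and 5 lower). Costimulation and maturation genes had a median of 0.09 at percentile 98.6 (11 called higher and 5 lower). No stimulation response was computed that would show which members of these lists LPS induced. Nor can a difference between single cultures be separated from genotype, because there was 1 stimulated KO library; a culture that met IFN-gamma or LPS later, or a different output of interferon, may give the same pattern. An effect of the loss of GOLPH2 on the interferon response stays open as an untested hypothesis.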

How the results depend on the processing

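Alternatives with an adjusted p of 0.05 or 1e-06, with a counting error no larger than that of 50 reads per library, all alternatives of list calls, and the additive model and its centring alternatives were chosen after seeing the data. Each state has 1 library per genotype, so no setting tests the spread between cultures within a state. Genes called by the additive model (503 higher, 469 lower) were 254 and 220 with centring on the median gene and 45 and 12 as deposited; without a filter (541 and 504) and with robust variances (480 and 407) they stayed within 1.5 times. The calls of 30 type I interferon members (29 to 31) and 22 interferon-gamma members (20 to 23) in stimulated cells stayed within 1.5 times under all settings run. Centring on the median gene moved no other count beyond 1.5 times.

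Counts at 2-fold are given as unstimulated higher and lower, then stimulated higher and lower (14, 13, 35 and 23). They were 63, 46, 65 and 91 at 1.5-fold, and 5, 3, 15 and 3 at 4-fold. With no evidence threshold they were 549, 485, 634 and 407, which adds genes of few reads. At an adjusted p of 0.05 they were 76, 43, 85 and 66, at 1e-06 they were 6, 6, 16 and 11, and at the counting error limit 8, 7, 19 and 14. As deposited, the first became 25. The authors' deposited calls (139, 22, 57 and 102) became 25, 10, 35 and 27 at 2-fold instead of 1.5-fold.

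For 1.5-fold calls (63, 46, 65 and 91), the ratios as deposited gave 140 and 22 in unstimulated cells, by the shift of 0.19 in their zero point. With no evidence threshold they were 1122, 872, 1052 and 1039, at 0.05 they were 178, 101, 156 and 178, and at 1e-06 the first 3 became 38, 26 and 35.

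Differences between states (22 higher, 19 lower) were 585 and 672 with no evidence threshold, 76 and 96 at 0.05, 8 and 11 at 1e-06, and 7 and 10 at the counting error limit; as deposited, 38 were lower. Genes 2-fold higher and lower in both states (9 and 4) were 114 and 60, 17 and 9, and 5 and 1 in the first 3 of these settings, and 2 were lower in both at the counting error limit, where r was 0.50 rather than 0.16 and rho 0.45 rather than 0.29. Stromal and endothelial members called higher in unstimulated cells (4) were 12, 7, 2 and 2 in the same 4 settings, and in stimulated cells (6) were 11 with no evidence threshold.

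As deposited, the medians of the inflammatory cytokine list (−0.14 to 0.047) and the Toll-like receptor and NF-kB list (−0.06 to 0.13) in unstimulated cells turned to above 0, by the same shift. So did all 8 unstimulated list medians below 0, which include those of the IL-12 (−0.06 to 0.14), Golgi (−0.03 to 0.16) and glycolysis lists (−0.05 to 0.14), and those of the interferon lists went from 0.05 to 0.24 and from 0.06 to 0.25. In stimulated cells 2 medians near 0 turned to below 0. At the counting error limit the median of the inflammatory cytokine list in unstimulated cells was −0.23, that of class I genes in stimulated cells −0.04, and that of neutrophil markers −0.25 in unstimulated (from −0.13) and 0.07 in stimulated cells (from −0.18). With 10 in place of 20 bins, all 50 list percentiles stayed on their side of the central 95%. Few reads limit low genes most, with a 90th percentile of the counting error of 0.964 in unstimulated cells. Prior counts, the floors of 10 and 200 reads, stimulation responses, the stimulation term of the additive model and its DESeq2 alternatives were not run.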

Other observations

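The tests of the fibroblast and endothelial lists and of counting error in this part were chosen after the results were seen; the test of the DNA around Golm1 was set before its result. In stimulated cells, genes of glycolysis and the hypoxia response were slightly lower in the KO library. Of 22 members, 16 were called lower and 2 higher (Gapdh and Hif1a), with a median of −0.11 at percentile 0.06; Pfkfb3, an activator of glycolysis, was at −0.44 ± 0.02 and Pdk1 at −0.35 ± 0.05. In unstimulated cells 7 were called lower and 4 higher. Genes of the unfolded protein response had 9 of 21 members called higher and 0 lower in stimulated cells, with Pdia4 at 0.33 ± 0.03 and Xbp1 at 0.29 ± 0.03. The medians of matched random lists there were 3 higher and 3 lower. In unstimulated cells 4 were called higher and 1 lower, near the random medians of 3 and 2. Oxidative phosphorylation genes had 5 of 25 called higher and 0 lower in stimulated and 3 and 0 in unstimulated cells, none by 1.5-fold. For this list, matched random lists had medians of 3 higher and 4 lower in stimulated and 2 and 2 in unstimulated cells.

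Genes of Golgi structure and glycosylation, the compartment of GOLPH2, stayed within 1.5-fold. In unstimulated cells 2 of 26 were called higher and 4 lower, and in stimulated cells 4 higher and 7 lower, with St3gal1 at −0.18 ± 0.01 and −0.21 ± 0.01. The medians of matched random lists were 3 higher and 3 lower in unstimulated cells, and 3 higher and 4 lower in stimulated cells. Cell cycle genes had 0 of 27 called in either state. Cholesterol biosynthesis genes had 2 of 20 called higher and 0 lower in each state. Immediate early and heat shock genes had 4 of 18 called higher and 1 lower in unstimulated cells, with Myc at 0.75 ± 0.13, and 4 and 2 in stimulated cells. Matched random lists had medians, in each state and direction, of 1 call for the cholesterol list and 2 for the immediate early list.

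Matrix and stromal genes higher in KO cells were examined with a list of 40 fibroblast markers, of which 10 were also in the stromal and endothelial list and all were listed in both tables. Counting error of low genes is argued against by the 13 members of the stromal and endothelial list, which was fixed before the data were examined. Of these, 4 were called higher in both states, where the central 95% of matched random lists ended at 1 and the highest of 10000 lists had 2. With a counting error no larger than that of 50 reads, 2 members were called higher in unstimulated and 5 in stimulated cells. The number called in both states was not compared with random lists at that limit. The endothelial list was not higher as a group in either state, for its 11 listed members, but it does not decide on endothelial cells. The bound set against this explanation, a median at or below that of random lists in 1 state, was met. In unstimulated cells the median was −0.19 at percentile 2.12, with 5 of 11 members above 0, 1 called higher and 1 lower. In stimulated cells it was 0.03 at percentile 51.4, near the random median of 0.02. There 6 of 11 members were above 0, with 0 called higher and 2 lower. The exact interval of the share above 0 in unstimulated cells (16.7% to 76.6%) includes 50%. That interval concerns the share and not the median, and treats the members as independent. The unstimulated median equals the lower end of the central 95% of random medians (−0.19), and the stimulated median lies near the random median. Meeting the bound therefore does not exclude endothelial cells. The list was added after seeing the data. Fibroblast-like cells in the KO cultures cannot be told apart from matrix expression by the cultured cells themselves. This explanation asked for at least 80% of the markers above 0 in both states, and under 80% in 1 state was set against it. The share was 82.5% in unstimulated and 75% in stimulated cells, so the bound set against it was met. An exact interval for stimulated cells (58.8% to 87.3%) includes 80%. That interval was added after the share was seen and treats the markers as independent. The list median was at percentile 100 in both states, as the explanation asked, so the result is mixed. Of the 40 markers, 11 were called higher and 2 lower in unstimulated cells, and 17 higher and 3 lower in stimulated cells. The 3, Pdgfrb (−0.74 ± 0.15), Mmp2 (−0.45 ± 0.10) and Col5a1 (−0.32 ± 0.07), are named after their values were seen, and genotype itself stays open.

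Genes that differ in both states the same way may come from passenger DNA around Golm1, carried along from the targeted chromosome. Within 10 Mb of Golm1, 5 of 144 other genes (3.47%) were called the same way in both states, among them Ctsl (0.41 in both states), against 5.19% in the median window elsewhere. This share lies at percentile 15.2 of 14476 windows, so genes called the same way, at any size, were not more frequent near Golm1 than elsewhere. The window could not hold most of the 768 such genes with a position, so the test does not decide their source. Passenger variants that act on genes outside the window were not tested. Variants elsewhere in the genome, and mice that gave the cultures of both states, were not tested and stay open beside genotype.

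The genes G530011O06Rik, Mx1, Isg15 and Iigp1 here, and Ctsl above, lie outside the rule for named genes and were chosen after their values were seen. On the X chromosome of GRCm38, Mid1 (169685199 to 169990798), the non-coding RNA gene G530011O06Rik (169975043 to 169978917), which lies inside Mid1 so that its value is uncertain, and Erdr1 (170010526 to 170018797) were all higher in the KO library in both states. Mid1 was at 3.04 and 2.31, G530011O06Rik at 1.03 and 0.85, and Erdr1 at 1.04 and 1.35. Capn11 (chromosome 17, 45630191 to 45659709) was lower by a like amount in both states, at −5.51 and −5.61. The interferon-induced genes Ifit2, Mx1, Isg15 and Iigp1 were among the 41 genes called in opposite directions, at 0.33, 0.32, 0.20 and 0.49 in unstimulated and −1.17, −0.64, −0.49 and −0.52 in stimulated cells.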
